A study of Homo sapiens with 8 samples.

How the data were processed

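Single cells from liver allograft core biopsies taken 12 months after living donor transplantation were sequenced from 4 patients given regulatory dendritic cell therapy (STUDY) and 4 reference patients on standard of care (SOC), 1 library per patient. Per the labels' protocols, biopsies taken with an 18 gauge needle were digested for 8 min at 37 °C in collagenase at 1 mg/ml, and all 8 libraries were prepared with the 10x Genomics single-cell 3' v3 kit, which captures messenger RNA at its polyadenylated end. The submitters' processing notes name hg38, Cell Ranger and Seurat 4.0, and the Cell Ranger version is not given in the sources used here. The deposited files hold raw counts of unique molecular identifiers (UMIs) per gene and barcode, unfiltered and with no normalization, per the file headers and their whole-number values. Libraries with the same replicate number came from different patients. In T cells the deviations of same-numbered libraries from their group means correlated at 0.128 to 0.159, above 0.1 in each of the 3 pairs, so the fit with the replicate number as a block is given beside the T cell result. In no other class did every pair exceed 0.1.

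The deposited gene lists differed between libraries. The 4 SOC libraries and STUDY replicates 2 and 3 listed 33538 genes, STUDY replicate 1 listed 32738 and STUDY replicate 4 listed 36601. The reference behind each list is not given in the sources used here, so the counts of STUDY replicates 1 and 4 may come from another genome build or annotation than those of the other libraries. Only the 30193 genes present in all 8 lists by Ensembl identifier were analysed, which held 98.8% to 99.8% of each library's UMIs. All 30193 were found by identifier in the GENCODE release 29 annotation of GRCh38, from which coordinates and exons were taken. Of these, 2196 share exonic sequence on the same strand with another gene of the SOC gene list. Cell Ranger leaves out reads that fit exons of more than 1 gene, so the counts of such genes depend on which other genes a reference lists and on which part of the transcript a library captures.

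A barcode was kept as a cell with at least 500 UMIs, at least 250 detected genes and at most 25% of UMIs from mitochondrially encoded genes, limits set before the data were examined. Scrublet (scanpy 1.11.5) marked 0.03% to 0.36% of cells per library as doublets. A caller that marks so few cells has not worked, so doublets remain in the data, and removal at the rate of 0.8% per 1000 cells was tried as an alternative. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were reduced to 30 principal components, and 3 nearest neighbours per cell were taken from each library so that the graph was balanced over libraries. Leiden clustering (leidenalg 0.10.2, igraph 0.11.9, resolution 1, fixed seed) gave the clusters, and clusters of T cells were clustered again. Clusters were named from markers fixed before the data were examined, and each named class is cell type-like in this sense only. The naming rule (at least 3 markers detected in 10% of cells, a mean scaled marker level above 0.5, no lead of another class's markers among the top 10 genes) was settled after the clusters had been seen and before any test between groups. Clusters that failed it stayed unnamed. Where the text gives the part of a class that a cluster held, the cells of a group's libraries were pooled. Such percentages lean on the libraries with most cells and were not tested between groups.

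The leading genes were CD3D, GZMK, IL7R and LTB in T cell clusters, IL2RB, KLRF1, XCL1 and GNLY in natural killer (NK) cells, CD79A and MS4A1 in B cells, S100A8, S100A9 and LST1 in monocytes, and C1QA, C1QB and HLA-DRA in macrophages. They were FCN3, CRHBP and IFI27 in endothelial cells, ALB, APOC3 and FABP1 in hepatocytes, KRT7 and DEFB1 in cholangiocytes, LILRA4 and TCF4 in plasmacytoid dendritic cells, HBB and ALAS2 in erythroid cells, and MKI67 and TOP2A in cycling cells. Among T cells, CD8A, CD8B and GZMK were among the leading genes of CD8 sub-clusters 1 and 2, while TNFRSF9, ID3, TIGIT and PDCD1 led CD8 sub-cluster 7, which had none of its markers among the top 10 and took its name from their mean level. CCR7, LEF1, CD40LG and CD4 were leading genes of the CD4 sub-clusters, and SLC4A10 and KLRB1 of the mucosal-associated invariant T (MAIT) sub-cluster.

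UMI counts were summed per library and class, and a class was tested with at least 20 cells in at least 3 libraries of each group. The 9 classes that qualified were compared, 1 fit each, with edgeR 4.0.16 in R 4.3.3 (trimmed mean of M-values normalization, its default expression filter, robust quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05 over all genes of the class). The standard error of a fold change is its size over the square root of the F statistic. STUDY replicate 4 had 10 T cells, so the T, CD8, CD4, NK and B cell fits compare 3 STUDY with 4 SOC libraries. On simulated counts at the real means and library sizes, with 200 genes changed, the T cell fit of 10785 genes recovered 36% of the 100 genes changed 2-fold and 94% of those changed 4-fold, with 3 false calls among 133. The monocyte fit of 7640 genes recovered 62% and 96%, with 9 false calls among 167. All simulated libraries came from the same mean profile per class, with the trended dispersion alone. They held no difference in chemistry or gene list, so recovery and false calls in the real fits may differ from these.

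The genes named in the text follow a rule fixed before the data were examined. For each class it takes up to 12 genes higher and 12 lower with the largest fold change among those past the threshold, at or above the median expression of the class, with an estimated free-RNA share of counts under 50%, and moving the same way in every fit that leaves out 1 library. It leaves out clone-based names, immunoglobulin and T cell receptor segments, genes whose level follows a person's genotype, and sex-linked transcripts. Where fewer than 5 genes of a class passed, the 5 with the smallest p were named as not passing, and for each gene list the members with the smallest p were named. Free RNA was estimated per library from barcodes with 1 to 100 UMIs, scaled by the hepatocyte transcripts found in each class, which gives an upper bound on its share. No such share was estimated for genes in hepatocytes. In that class neither the naming rule nor the removal of genes with a high free-RNA share left out any gene for free RNA.

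In all, 21 gene lists were fixed before the data were examined and tested where at least 5 members passed the filter, with camera in limma 3.58.1 at its preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over all 103 pairs of list and class. Camera with an estimated correlation, with and without the replicate number as a block, and fry were run beside it. Shares of cells were compared with exact two-sided permutation tests, 70 arrangements for 4 against 4 libraries and 35 for 3 against 4, with Benjamini-Hochberg adjustment over the shares. Intervals of single-library shares are exact 95% Clopper-Pearson intervals and cover counting error only. Within groups no libraries were duplicates, since chi-square per degree of freedom between libraries of a group ran from 3.71 to 58.2.

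The alternatives tried were DESeq2 1.42.0, limma-voom with sample quality weights, relative log expression (RLE) size factors, no expression filter, the replicate number as a block, other cell filters, doublet handling, class assignment by cell, an unbalanced graph, other minimum cell numbers, removal of genes with a high free-RNA share, and leaving out each library. Fits within 1 gene list (STUDY replicates 2 and 3 against SOC), within 1 barcode list (STUDY replicates 1 and 4 against SOC), of STUDY replicate 1 against SOC and without genes that share exons were also made. In the fit of STUDY replicate 1, that lone library is assumed to vary like the SOC libraries. T cell receptor beta UMIs in T cells were counted on variable and constant genes of each library's own gene list, except in STUDY replicate 1, whose list held 1 variable and 0 constant genes. This form replaced a count over the shared genes, which the differing lists had left without most variable genes. Author-made cell annotations were not used here. Some genes that the naming rule takes are not reported here.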

Results

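Liver allografts biopsied 12 months after living donor transplantation were profiled by single-cell RNA sequencing to compare patients given regulatory dendritic cell therapy (STUDY, n = 4) with reference patients on standard of care (SOC, n = 4). Regulatory dendritic cells are dendritic cells prepared to dampen T cell responses rather than to start them, and the comparison asks whether the cells of the graft differ in number or in expression after such therapy. Each patient gave 1 library. The STUDY libraries held 11044528 to 87441965 UMIs in all and the SOC libraries 33892071 to 57100301. Filtering left 23499 cells, between 275 in STUDY replicate 4 and 4785 in SOC replicate 4. Median depth was 1979 to 4221 UMIs per cell in STUDY libraries and 3261 to 3936 in SOC libraries.

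The STUDY libraries also differed from the SOC libraries in how they were made and counted. STUDY replicates 2 and 3 used a list of 737280 barcodes, of which 10.5% occur on the list of 6794880 barcodes that fits STUDY replicates 1 and 4 and all SOC libraries. In T cells, 67.6% (95% Clopper-Pearson interval 66.6 to 68.7) and 56.6% (54.5 to 58.6) of T cell receptor beta UMIs of STUDY replicates 2 and 3 lay on variable genes, at the 5' end of the transcript. The SOC libraries had 2.96% to 6.52% there, and STUDY replicate 4 had 3.85% (0.10 to 19.6) in 10 T cells. The capture end of STUDY replicate 1 was not measured, because its gene list held 1 variable and 0 constant genes. STUDY replicates 1 and 4 were each counted on a gene list of their own, while all other libraries shared a single list, and another genome build or annotation is not excluded for those 2 libraries. No STUDY library shared both the gene list and the barcode list of the SOC libraries, so that therapy and technique cannot be told apart in any pooled comparison, and fits within 1 list are given beside the pooled ones.

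T cells were the most abundant class on average, with a share of 50.5% ± 9.49 (SD, n = 4) of SOC cells and 33.5% ± 28.4 (SD, n = 4) of STUDY cells. NK cells made up 18.0% ± 16.7 of STUDY and 13.6% ± 3.79 of SOC cells, monocytes 9.70% ± 4.90 and 6.12% ± 3.65, and B cells 3.20% ± 1.58 and 4.96% ± 3.65 (SD, n = 4 each). Macrophages, resident phagocytes of the liver together with recruited ones, averaged 9.24% ± 7.55 in STUDY and 4.09% ± 0.565 in SOC libraries (SD, n = 4). Hepatocytes, the parenchymal cells, took 10.2% ± 5.89 and 11.1% ± 5.74, and endothelial cells 5.10% ± 6.30 and 3.55% ± 0.982. Cholangiocytes of the bile ducts took 2.38% ± 3.51 and 0.845% ± 0.779, plasmacytoid dendritic cells 0.988% ± 1.05 and 0.443% ± 0.195, cycling cells 3.07% ± 2.92 and 1.32% ± 0.390, and erythroid cells 0.809% ± 0.358 and 1.06% ± 0.910. The unnamed clusters, led by KLRB1 and NKG7 at low depth or by CST3 and HLA-DRA, held 3.92% ± 2.75 of STUDY and 2.51% ± 0.646 of SOC cells.

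No share passed the test against the spread between patients. The smallest exact two-sided permutation p was 0.114, for macrophages, and the smallest adjusted p over the 12 shares was 0.814, where 4 against 4 libraries can reach 0.0286. The macrophage excess came largely from STUDY replicate 4, in which 20.4% of 275 cells (15.8 to 25.6) were macrophages and 3.64% (1.76 to 6.59) were T cells. Of its 56 macrophages 54 lay in cluster 11, led by HLA-DRA, CST3 and LYZ, whose markers ranked dendritic cells second after macrophages (1.55 against 2.19 in mean scaled level). With at most 10% mitochondrial UMIs a cluster led by those 3 genes was named dendritic cell, although it held no cell of that library, so the name of the 54 cells is uncertain. Without that library the macrophage difference was 1.44 instead of 5.15 percentage points and the T cell difference -7.01 instead of -17.0. The limit on mitochondrial UMIs sets the shares of that library, whose kept cells numbered 275 at 25% and 2361 at 50%, a rise of 8.59 times against 1.09 to 1.32 times in SOC libraries.

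**Figure D1:**
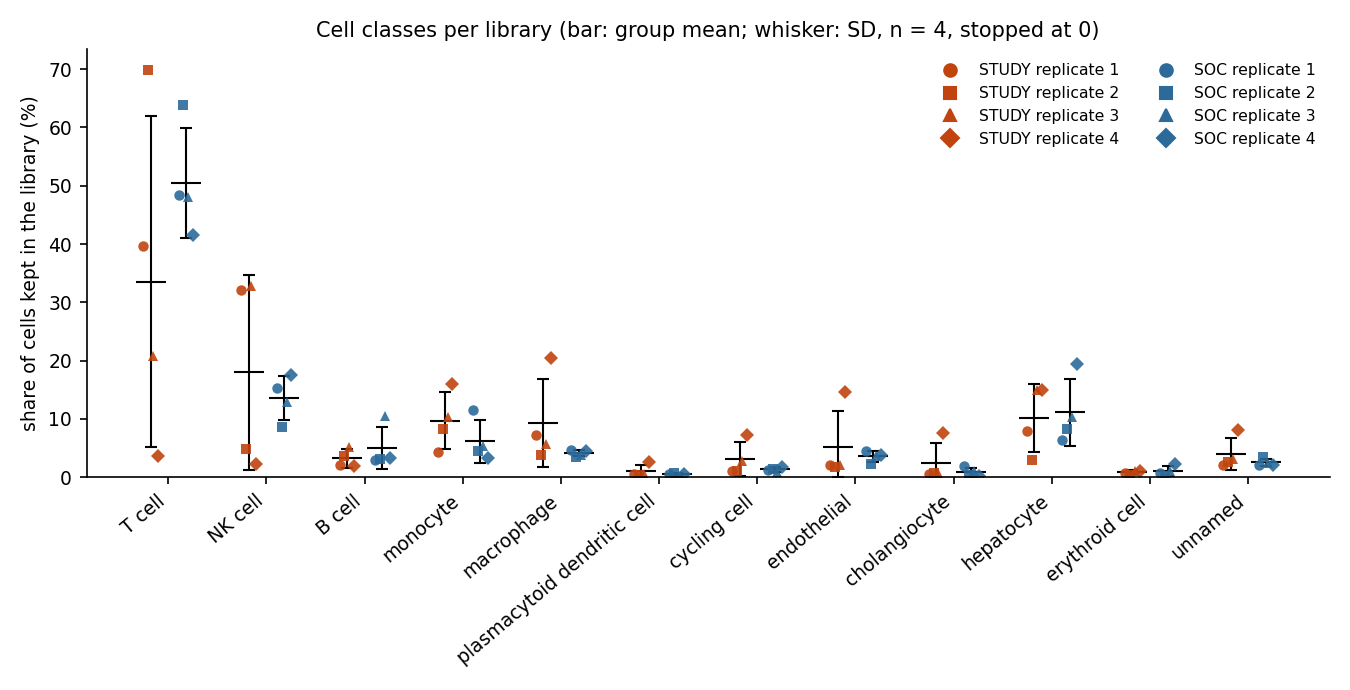
Share of each cell class among the cells kept, in percent, for every library. Points are libraries, horizontal bars group means and whiskers SD (n = 4 per group). STUDY replicate 4, with 275 cells, lies at 20.4% macrophages and 3.64% T cells.

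Among T cells, cytotoxic-lineage CD8 T cells made up 39.0% ± 7.33 (SD, n = 3) in STUDY and 34.6% ± 13.6 (SD, n = 4) in SOC libraries, and helper-lineage CD4 T cells 22.0% ± 11.3 and 23.3% ± 4.51. MAIT cells, which recognise microbial riboflavin metabolites and are abundant in liver, made up 1.91% ± 1.77 of STUDY and 11.1% ± 13.5 of SOC T cells. The SOC mean rested on SOC replicate 3, where 31.1% (28.9 to 33.4) of T cells were MAIT cells. The share was lower in STUDY in all 3 pairs of libraries with the same number (1.07% against 6.68%, 0.713% against 1.70% and 3.95% against 31.1%), and an exact test over 3 pairs cannot pass the threshold. The numbers do not pair patients, and unpaired the groups overlapped, with 3.95% in STUDY replicate 3 and 1.70% in SOC replicate 2. Exact permutation p-values were 0.743, 0.857 and 0.114 (3 against 4 libraries, smallest possible 0.0571), and no subset passed after adjustment. The 4 unnamed T cell sub-clusters held 14.7%, 20.2%, 1.53% and 0.620% of STUDY and 17.9%, 10.4%, 2.12% and 0.580% of SOC T cells. The first, sub-cluster 0, was led by GNLY and FGFBP2 and ranked CD8 T cells first by markers, at a mean scaled level of -0.07. It may hold CD8 T cells that the CD8 share leaves out. The others were led by the NK cell genes KLRF1 and TYROBP, by ALB and APOC3, and by C1QA and C1QB. The T cell class therefore holds some cells with transcripts of other types.

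In T cells, the highest fold change belonged to PTPRCAP, which encodes a partner of the CD45 phosphatase. It stood at 453 ± 406 CPM (counts scaled to the same library total; SD, n = 3) in STUDY and 0.805 ± 0.282 (n = 4) in SOC libraries, a log2 fold change of 9.07 ± 0.74 (SE). The glycolytic enzyme ALDOA rose by 4.12 ± 0.41, POLD4, a subunit of DNA polymerase delta, by 3.70 ± 0.30, and the excision repair nuclease ERCC5 by 2.58 ± 0.27. COX16, AGGF1, the purine synthesis enzyme ADSL, the DNA repair gene RAD50 and SLC35E2B also rose, by 1.43 to 2.38. KIAA0355 (also named GARRE1) was the gene named as lower, with a log2 fold change of -2.28 ± 0.27 (6.77 ± 1.07 against 34.4 ± 9.003 CPM). In all, 30 of 10987 genes passed in edgeR's quasi-likelihood test (adjusted p 0.00285 to 0.0450 for those named), 24 higher and 6 lower in STUDY, and 2517 had an unadjusted p under 0.05. The groups did not overlap in 19.3% of genes, against 5.7% by chance. With cells pooled over libraries, cluster 0, led by CD3D and GZMK, held 46.8% of STUDY and 28.3% of SOC T cells. Cluster 1, led by GNLY and GZMH, was the largest in SOC with 33.8% against 25.8%.

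Most of these genes share exonic sequence with another gene on the same strand, which makes their counts uncertain. This held for 22 of the 30 genes called in T cells (73.3%) and for 10.7% of the others tested. PTPRCAP (ENSG00000213402, chromosome 11, 67435510 to 67438067, GRCh38) shares a stretch of 841 exonic bases with CORO1B. ALDOA (ENSG00000149925, chromosome 16, 30064164 to 30070457) and POLD4 (ENSG00000175482, chromosome 11, 67350777 to 67356972) share stretches of 304 and 448 bases with clone-named genes that STUDY replicate 1 was not counted on, and COX16 (chromosome 14, 70325081 to 70359731) shares 386 with the readthrough gene SYNJ2BP-COX16. KIAA0355 (ENSG00000166398, chromosome 19, 34254537 to 34355586) shares none. Leaving out such genes left 2 calls in T cells, KIAA0355 and the glycoprotein gene GPM6A. The latter does not pass the naming rule and is named because the count is small. Of the 30 calls, 2 had an estimated free-RNA share of 50% or more. The folds of the 8 called genes without a shared exon moved by at most 0.005 log2 units there, and the adjusted p of the 6 that lost the call rose to at most 0.109. Within the gene list of the SOC libraries, STUDY replicates 2 and 3 gave 3550 calls (1759 higher and 1791 lower), which is also the count without STUDY replicate 1, and STUDY replicate 1 alone gave 135 (57 higher and 78 lower). Without SOC replicate 1, 2, 3 or 4 the count fell to 14, 17, 16 and 16, and COX16, RAD50 and SLC35E2B lost the call in 4 of the 7 fits that left out 1 library. With the replicate number as a block 25 genes passed, 15 higher and 10 lower, and 17 of them were among the 30. With the block the log2 fold change of COX16 in T cells was 2.10 (edgeR adjusted p 0.166), the log2 fold change of RAD50 in T cells 1.91 (0.0932) and the log2 fold change of SLC35E2B in T cells 1.44 (0.115), and none of these passed. The size of the largest folds rested in part on STUDY replicate 1: without it the log2 fold change of PTPRCAP in T cells was 7.999, the log2 fold change of ALDOA in T cells 3.40 and the log2 fold change of COX16 in T cells 1.64.

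CD8 T cells had 41 of 8865 genes past the threshold, 33 higher and 8 lower, with 1807 at an unadjusted p under 0.05. ZNF683 (Hobit, a transcription factor of tissue-resident lymphocytes; chromosome 1, 26361634 to 26374522) rose by 2.46 ± 0.41, from 9.89 ± 4.25 to 48.9 ± 30.6 CPM (edgeR adjusted p 0.0301). The T cell receptor kinase ZAP70, the potassium channel KCNA3 and the inhibitory receptor CD5 rose by 1.51 ± 0.27, 1.56 ± 0.31 and 1.502 ± 0.29. GIMAP5, a GTPase of lymphocyte survival, and the nuclear matrix gene MATR3 rose by 2.20 ± 0.30 and 2.18 ± 0.34, beside PTPRCAP, ALDOA, POLD4, COX16 and ADSL as in all T cells. Lower in STUDY were KIAA0355 (-2.24 ± 0.35), the phospholipase gene PLCB1 (-1.73 ± 0.33), the linker histone gene HIST1H1D (-1.53 ± 0.29), TIMM10 (-1.39 ± 0.28), a chaperone of mitochondrial protein import, and the nucleolar gene NOL7 (-0.997 ± 0.20). ZNF683, ZAP70, KCNA3, CD5 and these 5 lower genes share no exon with another gene. With cells pooled over libraries, sub-cluster 1, led by GZMK and CD8B, held 67.3% of STUDY CD8 T cells. Sub-cluster 2, led by CD8B and NKG7, held 53.7% of those of SOC. The latter rested largely on SOC replicate 2, with 402 cells in sub-cluster 1 and 898 in sub-cluster 2. The cells numbered 264 and 296, 273 and 194, and 193 and 157 in SOC replicates 1, 3 and 4.

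Without genes that share exons, 0 genes passed in CD8 T cells, although the folds of the 20 remaining genes moved by at most 0.009 log2 units and only their adjusted p rose, to at most 0.0783. Within the SOC gene list STUDY replicates 2 and 3 gave 2280 calls (1115 higher and 1165 lower, the count without STUDY replicate 1), and STUDY replicate 1 alone gave 107 (54 and 53). The count was 13, 12, 15 and 17 without SOC replicates 1 to 4, 27 without STUDY replicate 2 and 24 without STUDY replicate 3. ZAP70, KCNA3, CD5, HIST1H1D, TIMM10 and NOL7 each lost the call in 6 of the 7 fits that left out 1 library, PLCB1 in 5, COX16 and MATR3 in 4, and ZNF683, PTPRCAP and ALDOA in 3. Without STUDY replicate 1 the log2 fold change of ZNF683 in CD8 T cells was 1.76 and the log2 fold change of MATR3 in CD8 T cells 1.45, while the log2 fold change of KIAA0355 in CD8 T cells was -2.86.

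In CD4 T cells 19 of 8588 genes passed in edgeR, 17 higher and 2 lower, with 1246 at an unadjusted p under 0.05. ZAP70 rose by 1.62 ± 0.29 and PSMB10, an immunoproteasome subunit, by 1.54 ± 0.28, together with PTPRCAP, ALDOA, POLD4, COX16, RAD50 and ADSL (2.11 to 9.12). HIST1H1D fell by 1.81 on the log2 scale, from 357 ± 37.7 CPM (SD, n = 4) in SOC to 96.7 ± 41.2 (SD, n = 3) in STUDY libraries. Of the 19 genes 16 share exons, and HIST1H1D was the 1 call left without them. ZAP70 and KIAA0355, which share none, moved by at most 0.008 log2 units there, and their adjusted p rose to at most 0.126. ZAP70 and PSMB10 lost the call in 6 of the 7 fits that left out 1 library. With cells pooled over libraries, sub-cluster 5, led by CD40LG, held 62.8% of STUDY CD4 T cells. Sub-cluster 4, led by IL7R and CCR7, held 64.4% of those of SOC. Single libraries differed in this. Sub-clusters 4 and 5 held 71 and 45 cells in STUDY replicate 3, 6 and 0 in STUDY replicate 4 and 187 and 315 in SOC replicate 1. STUDY replicates 1 and 2 and SOC replicates 2 to 4 went with the pooled values. As shares of T cells neither sub-cluster passed (exact permutation p 0.4 and 0.457). STUDY replicates 2 and 3 gave 1319 calls within the SOC gene list (585 higher and 734 lower, the count without STUDY replicate 1) and STUDY replicate 1 alone 104 (50 and 54), and the count was 12, 10 and 12 without SOC replicates 1, 2 and 3.

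In NK cells 19 of 9008 genes passed in edgeR, 16 higher and 3 lower, with 1408 at an unadjusted p under 0.05. TCIRG1, a subunit of the vacuolar proton pump, rose by 1.11 ± 0.19 (127 ± 16.2 against 57.3 ± 8.89 CPM), with PTPRCAP, POLD4 and MATR3 at 2.25 to 9.01. IL18R1, a chain of the interleukin-18 receptor (chromosome 2, 102311529 to 102398775), fell by 1.27 on the log2 scale, from 59.4 ± 11.3 to 23.4 ± 3.52 CPM (adjusted p 0.0443), and KIAA0355 fell by 1.90. IL18R1 and TCIRG1 share stretches of 95 and 155 exonic bases with IL1RL1 and a clone-named gene, and 0 genes passed in edgeR without such genes. The folds of the 4 called genes that share no exon moved by at most 0.007 log2 units there, and their adjusted p rose to at most 0.1495. IL18R1 lost the call in 6 of the 7 fits that left out 1 library, TCIRG1 and KIAA0355 in 5, and PTPRCAP and MATR3 in 4. STUDY replicates 2 and 3 gave 2204 calls within the SOC gene list (1022 higher and 1182 lower, the count without STUDY replicate 1) and STUDY replicate 1 alone 169 (70 and 99). The count was 1, 1, 5 and 3 without SOC replicates 1 to 4, 9 without STUDY replicate 2 and 37 without STUDY replicate 3.

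In B cells 17 of 5118 genes passed in edgeR, 12 higher and 5 lower, with 780 at an unadjusted p under 0.05. HIST1H1D (chromosome 6, 26234268 to 26234933), a histone gene whose main transcript ends without a poly(A) tail, fell by 2.52 on the log2 scale, from 265 ± 42.6 CPM (SD, n = 4) to 46.5 ± 6.05 (SD, n = 3; adjusted p 0.000579). YBX3, an RNA-binding protein gene, and TNFRSF13C, the receptor of the B cell survival factor BAFF (chromosome 22, 41922023 to 41926818), fell by 2.27 and 1.38. PLD4, an endolysosomal nuclease, rose by 2.06 ± 0.38, the tetraspanin CD82 by 1.81 ± 0.34, PSMB10 by 1.70 ± 0.33 and SND1 by 1.37 ± 0.26, beside PTPRCAP, ALDOA and POLD4. Of the 17 genes 10 share exons, and HIST1H1D was the 1 call left without them. The folds of the other 6 moved by at most 0.006 log2 units there, and their adjusted p rose to at most 0.0957. PLD4, CD82, PSMB10, SND1 and TNFRSF13C each lost the call in 6 of the 7 fits that left out 1 library, and YBX3 in 4. STUDY replicates 2 and 3 gave 709 calls within the SOC gene list (312 higher and 397 lower, the count without STUDY replicate 1) and STUDY replicate 1 alone 29 (17 and 12). The count was 6, 5, 7 and 6 without SOC replicates 1 to 4 and 6 and 9 without STUDY replicates 2 and 3.

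**Figure D2:**
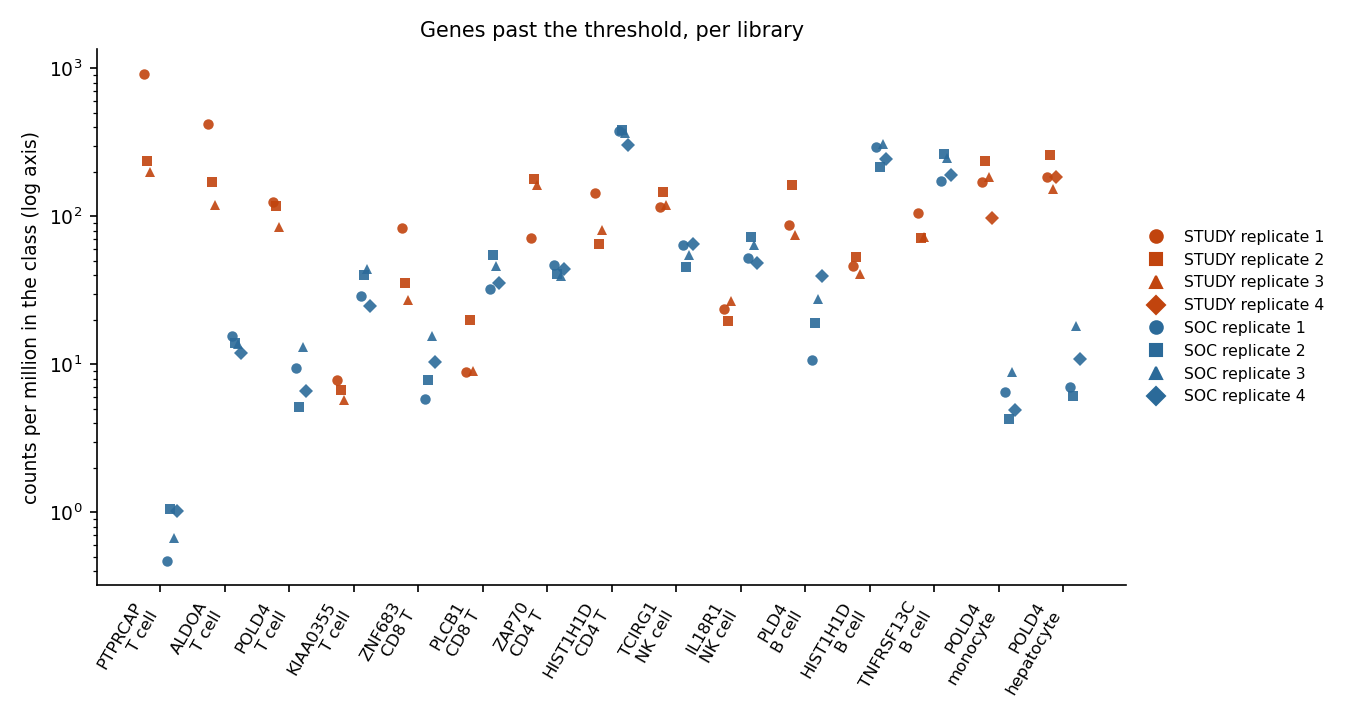
CPM (log axis) of genes past the threshold in the cell class named under each, 1 point per library. HIST1H1D in B cells averages 46.5 in STUDY and 265 in SOC libraries, and STUDY replicate 4 has points only in monocytes and hepatocytes.

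In monocytes 5 of 7853 genes passed in edgeR, all higher in STUDY, with 1644 at an unadjusted p under 0.05. POLD4 rose by 4.84 ± 0.28 (173 ± 57.9 against 6.12 ± 2.02 CPM; SD, n = 4) and COX16 by 2.58 ± 0.30. The other calls, ERCC5 (2.87 ± 0.33), the acyltransferase MBOAT1 (2.51 ± 0.40) and ADSL (1.86 ± 0.29), lay below the median expression of the class, and MBOAT1 alone shares no exon. The ion pump gene ATP13A3 (-1.63 ± 0.29) did not pass (adjusted p 0.0508). With RLE size factors 8 genes passed, 7 higher and 1 lower. With cells pooled over libraries, cluster 6, led by S100A9 and S100A8, held 73.3% of STUDY and 91.9% of SOC monocytes. Cluster 16, led by LST1, AIF1 and FCGR3A, held 26.7% and 8.1%. Within the SOC gene list 1437 genes passed (757 higher and 680 lower) and within its barcode list 47 (26 and 21), and the count was 878 without STUDY replicate 1, 12 without STUDY replicate 3, 17 without STUDY replicate 4, 3 without SOC replicate 2 and 9 without SOC replicate 4. DESeq2 called 2 of the 5 genes and gave no adjusted p for the other 3.

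In macrophages 7 of 6629 genes passed in edgeR, all higher, with 674 at an unadjusted p under 0.05, and all 7 share exons with another gene. POLD4 rose by 4.06 ± 0.33 and COX16 by 2.90 ± 0.40, and CLN6, RAD50, ADSL and AGGF1, below the median expression, by 1.62 to 3.27. IL10RB, a chain of the interleukin-10 receptor, did not pass (3.99 ± 0.69, adjusted p 0.110). With cells pooled over libraries, cluster 11, led by HLA-DRA and CST3, held 59.3% of STUDY macrophages. Cluster 10, led by C1QB and FTL, held 60.2% of those of SOC. Within the SOC gene list 686 genes passed (336 higher and 350 lower) and within its barcode list 19 (17 and 2, with 6 of the 7), and the count was 57 without STUDY replicate 1 and 4, 3, 3 and 2 without SOC replicates 1 to 4.

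Endothelial cells had 1 gene past the threshold among 5017, POLD4 (3.54 ± 0.44, edgeR adjusted p 0.00406), with 360 at an unadjusted p under 0.05. It was called in 7 of the 8 fits that left out 1 library and did not pass the expression filter in that without STUDY replicate 1. Within the SOC gene list the log2 fold change of POLD4 in endothelial cells was 2.36 and did not pass (adjusted p 0.308), while within the barcode list it passed (3.89, 0.000670). The cytokine gene MIF (1.93 ± 0.34, adjusted p 0.131), GIMAP5 (1.82 ± 0.39) and the hepatocyte gene APOC1 (-1.70 ± 0.37) did not pass, and free RNA could make up at most a fraction of 0.966 of the counts of APOC1. Within the SOC gene list 25 genes passed (12 higher and 13 lower) and within its barcode list 13 (8 and 5), and the count was 8 without STUDY replicate 1 and 2 without STUDY replicate 3, STUDY replicate 4 or SOC replicate 4.

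In hepatocytes 4 of 4386 genes passed in edgeR, all higher, with 403 at an unadjusted p under 0.05, and all 4 share exons with another gene. They included POLD4 (4.05 ± 0.34), COX16 (2.81 ± 0.41) and, below the median expression, the adenylate kinase gene AK1 (3.34 ± 0.52). GLUL, the glutamine synthetase of pericentral hepatocytes, stood at 1090 ± 594 CPM in STUDY and 316 ± 39.97 in SOC libraries (SD, n = 4) and did not pass (log2 1.76 ± 0.34, adjusted p 0.110). RAD50 (2.22 ± 0.45) and AGGF1 (1.94 ± 0.42) did not pass either. Within the SOC gene list 247 genes passed (114 higher and 133 lower) and within its barcode list 8 (all higher). The former held 2 of the 4 calls, since the log2 fold change of AK1 in hepatocytes was 2.58 there and did not pass (adjusted p 0.0665), and the latter held all 4. DESeq2 called none of the 4 and gave no adjusted p for any of them. The count was 2 without any 1 of the SOC libraries, 40 without STUDY replicate 1, 9 without STUDY replicate 3 and 11 without STUDY replicate 4.

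Of 103 pairs of gene list and cell class, 16 passed in camera, 3 higher and 13 lower in STUDY. None passed with an estimated correlation or in fry (adjusted p = 0.955 with an estimated correlation for all 16), where 2 and 8 pairs had an unadjusted p under 0.05. Of the 16 pairs 13 concerned lists included as checks of RNA quality, chemistry or other cell types. In 22 of the 103 pairs, none of them among the 16, the signs of median, mean and test differed.

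The ribosomal protein genes, 34 components of the ribosome, were lower in STUDY in 7 of 9 classes. Their median log2 fold change was -0.67 in hepatocytes (adjusted p 2.31e-20), -0.62 in CD4 T cells, -0.64 in B cells, -0.58 in CD8 T cells, -0.56 in T cells, -0.35 in NK cells and -0.17 in macrophages. No single ribosomal gene passed over all genes, and adjusted over the list alone 24 were lower in hepatocytes, 23 in CD4 T cells, 21 in T cells and 18 in CD8 T cells. In B cells, NK cells and macrophages none passed over the list alone, and 1 member was higher in CD4 T cells and in T cells. In monocytes the list did not pass and its median was 0.12, with 23 of 34 members above 0, and in endothelial cells the median was 0.01. In macrophages the ribosomal proteins (RNA quality and chemistry check) list did not pass without SOC replicate 2 (adjusted p 0.307), without STUDY replicate 1 (0.0861) or within the SOC gene list (0.0798). In T cells the median lay at -0.74 in the fit of STUDY replicates 2 and 3 and at -0.23 in that of STUDY replicate 1. In NK cells STUDY replicate 1 lay 0.02 above the SOC mean, and its fit gave an adjusted p of 0.629 for the list.

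**Figure D3:**
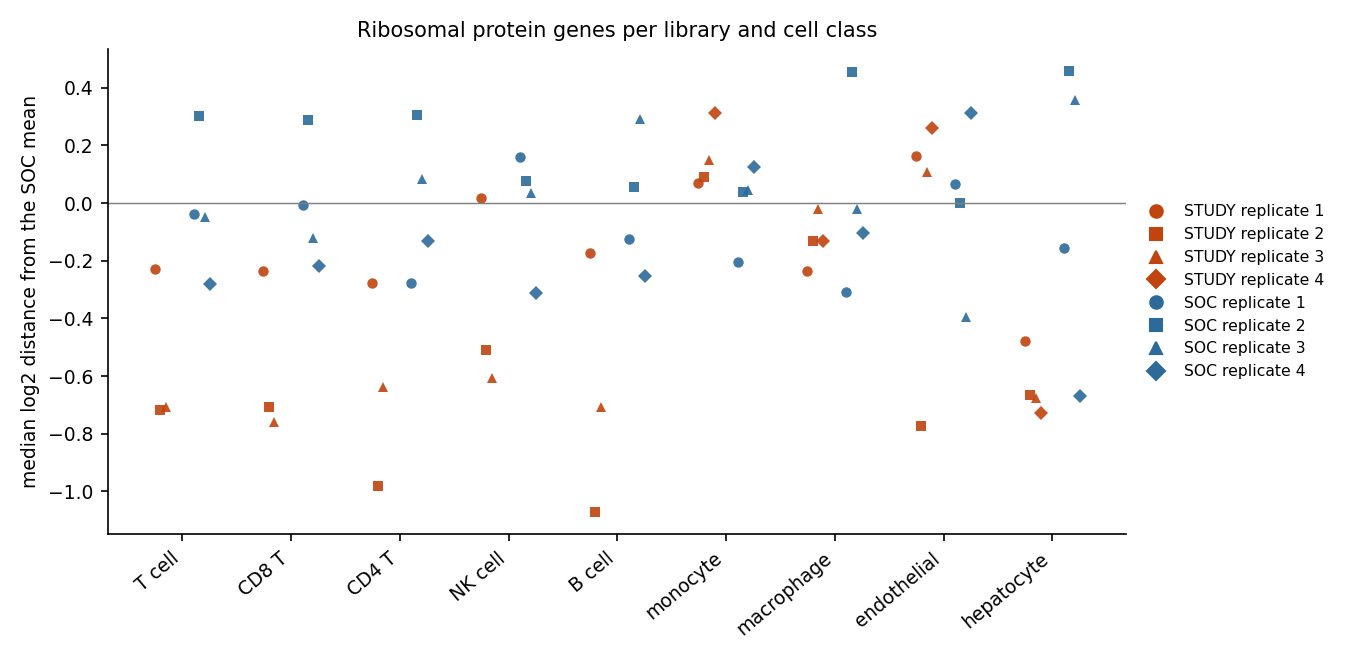
Median log2 distance of 34 ribosomal protein genes from the SOC mean, 1 point per library and cell class. Each SOC library is measured from the mean of the other SOC libraries, which widens the SOC range. In T cells STUDY replicates 2 and 3 lie at -0.72 and -0.71, STUDY replicate 1 at -0.23 and the SOC libraries between -0.28 and 0.30.

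Transcripts of hepatocytes, which reach other cells as free RNA, were lower in STUDY endothelial cells (median -1.14, adjusted p 5.07e-10), macrophages (-0.64, 0.000711) and T cells (-1.20, 0.00726). No member passed over all genes, and adjusted over the list alone 8 of 10 were lower in endothelial cells, among them ALB (-1.60 ± 0.35) and HP (-1.24 ± 0.33). Hepatocyte transcripts made up 0.035% to 0.169% of the UMIs of STUDY and 0.184% to 0.252% of those of SOC endothelial cells. In T cells the hepatocyte transcripts (other cell type and free RNA check) list did not pass without STUDY replicate 1 (0.0585), without STUDY replicate 2 (0.252) or within the SOC gene list (0.0624).

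The 13 mitochondrially encoded genes were higher in endothelial cells (median 0.43, adjusted p 0.00619) and monocytes (0.59, 0.0298) and lower in CD4 T cells (median -0.45, 0.0470). STUDY replicate 4 stood apart, with 21.6% mitochondrial UMIs in monocytes (9.47% to 11.9% in the other libraries) and 18.7% in endothelial cells (11.2% to 14.6%). Without it the mitochondrially encoded (RNA quality check) list did not pass in monocytes (adjusted p 0.600) or endothelial cells (0.125), nor within the SOC gene list (0.824 and 0.0916), and in monocytes it did not pass without SOC replicate 2 (0.0631) either. In CD4 T cells it did not pass without STUDY replicate 2 (0.117) or SOC replicate 1, 3 or 4 (0.0660, 0.136 and 0.0953). MT-ATP8 and MT-ND4L were at 3.29 ± 1.04 and 2.11 ± 0.61 in CD4 T cells while MT-ATP6 was at -1.05 ± 0.33, none passing.

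The cytotoxic effector list, granule and killer cell genes, was lower in STUDY CD8 T cells (17 members, median -0.52, adjusted p 0.00726). No member passed over all genes, and adjusted over the list alone the NK receptor gene KLRD1 (-1.08 ± 0.23) was lower. FCGR3A (-1.41 ± 0.58), GZMM (-0.55 ± 0.25) and CX3CR1 (-1.95 ± 0.81) did not pass. The list no longer passed without STUDY replicate 3 (adjusted p 0.0879) or with STUDY replicate 1 alone (0.106). In the same CD8 T cells the ribosomal list was lower (median -0.58), and sub-cluster 1 held 67.3% of the STUDY and 39.3% of the SOC cells. Neither difference was separated from that of the cytotoxic list. The CD8 class left out unnamed T cell sub-cluster 0, with 1970 cells led by GNLY, FGFBP2 and GZMB, so the CD8 result does not cover those cells. Of the 1545 SOC cells of sub-cluster 2, 898 came from SOC replicate 2. In NK cells GZMM (-0.85 ± 0.21) was lower over the list alone, and the list did not pass (adjusted p 0.0874).

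The type I interferon response list was lower in STUDY macrophages (27 members, median -0.42, adjusted p 0.00165), where hepatocyte transcripts were lower too. No member passed over all genes or adjusted over the list alone, and IFI27 (-0.86 ± 0.27), ISG20 (-1.59 ± 0.55) and RSAD2 (-1.04 ± 0.40) had the smallest p. The list did not pass without SOC replicate 1 (0.502), without STUDY replicate 1 (0.371) or within the SOC gene list (0.199). In the same macrophages the ribosomal list was lower, and cluster 11 held 59.3% of the STUDY and 39.8% of the SOC cells. Neither difference was separated from that of the interferon list. In T cells it passed, lower in STUDY, in camera with the replicate number as a block (adjusted p 0.00835) and not without it (0.298). The type I interferon response list in T cells had an adjusted p = 0.983 with an estimated correlation and the block, and an adjusted p = 0.955 with an estimated correlation without it.

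The MHC class II presentation list, genes that present antigen to CD4 T cells, was higher in STUDY hepatocytes (5 members, median 0.77, adjusted p 0.00619). The invariant chain gene CD74 (2.21 ± 0.57; 177 ± 168 against 39.1 ± 14.8 CPM) was higher over the list alone, while HLA-DRA (1.30 ± 0.58) and HLA-DPA1 (0.77 ± 0.48) did not pass. Over the list alone CD74 was also higher in T cells (1.78 ± 0.41), CD8 T cells (1.67 ± 0.42), NK cells (1.83 ± 0.44) and B cells (1.85 ± 0.41; 12900 ± 7879 against 3580 ± 466 CPM), and the protease gene CTSS was lower in T, CD8 T and NK cells (-0.69 to -0.77). With the graph not balanced, CD74 was a leading gene of a CD8 sub-cluster of 929 cells, 689 from STUDY replicate 2 and 234 from STUDY replicate 3. Its rise in lymphocytes was not separated from the technique of those libraries. In hepatocytes the list did not pass without SOC replicate 3 (0.0677), without STUDY replicate 1 (0.0587) or within the SOC gene list (0.113), and it turned direction with classes assigned per cell (0.992). The leukocyte genes CD3D (-0.80 ± 0.81; 50.4 ± 69.2 against 113 ± 48.5 CPM) and PTPRC (-0.40 ± 0.39), chosen after their values were seen, were measured in the hepatocyte class and did not pass, and hepatocyte cluster 19 ranked T cells second by markers. Neither gene is particular to macrophages, led by HLA-DRA among others, or to B cells, where CD74 stood high. Whether transcripts of those cells reached the hepatocyte class therefore cannot be told from them. The ribosomal list was lower in the same hepatocytes (median -0.67), and that difference was not separated from that of the MHC class II list.

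The lists of checkpoint and exhaustion, regulatory T cell, naive and central memory T cell, and tissue residency genes passed in no class, with lowest adjusted p of 0.422, 0.754, 0.111 and 0.422. In CD8 T cells 1 of 11 tissue residency genes, ZNF683, passed over all genes, and adjusted over the list alone CXCR3 (0.81 ± 0.19) and CXCR6 (0.59 ± 0.22) were also higher and RGS1 (-0.81 ± 0.29) lower. CXCR3 (0.86 ± 0.19) and the checkpoint list's NR4A2 (1.67 ± 0.37) were higher over the list alone in T cells. With the graph not balanced, NR4A2 was a leading gene of a CD8 sub-cluster of 929 cells, 689 from STUDY replicate 2 and 234 from STUDY replicate 3. Its rise was not separated from the technique of those libraries. In CD4 T cells IKZF2 (-2.19 ± 0.65), IL7R (-0.86 ± 0.24), HOPX (-0.69 ± 0.20) and KLRD1 (-1.64 ± 0.46) were lower over the list alone. MHC class I presentation (0.197), inflammatory cytokine and NF-kB (0.0693), tolerogenic myeloid (0.826), dissociation stress (0.200), glucocorticoid response (0.0922), proliferation (0.695), acute phase (0.108), drug and bile acid metabolism (0.498) and endothelial activation (0.739) did not pass in any class either. Adjusted over the list alone, ICAM1 (1.44 ± 0.34), TNFAIP3 (1.39 ± 0.41) and NFKBIZ (0.74 ± 0.26) were higher in T cells, CCL2 (2.58 ± 0.70) was higher in endothelial cells and MAF (-1.33 ± 0.36) was lower in monocytes. Of the inflammatory list, TNFAIP3 was also higher in CD8 T cells (1.85 ± 0.37), CD4 T cells (1.54 ± 0.38) and NK cells (0.92 ± 0.34), ICAM1 in NK cells (0.93 ± 0.29) and TNF in monocytes (0.77 ± 0.24). NFKB1 was lower in NK cells (-0.80 ± 0.26) and PTGS2 in monocytes (-1.16 ± 0.37), so the members moved in both directions. HLA-F was lower in endothelial cells (-1.24 ± 0.28) and KLF6 higher in B cells (0.94 ± 0.26) and NK cells (0.77 ± 0.20) over the list alone. PSMB10, which shares exons with another gene, was higher over the list alone in 8 classes, and FKBP5, a glucocorticoid-induced co-chaperone that also binds tacrolimus, was lower in CD8 T cells (-1.02 ± 0.28), NK cells (-1.48 ± 0.33) and monocytes (-1.16 ± 0.31). Of the same glucocorticoid list, MT2A (-0.75 ± 0.24) was lower and ZBTB16 (0.61 ± 0.23) higher in NK cells, CXCR4 (-0.97 ± 0.28) was lower in B cells, and DDIT4 (1.05 ± 0.34) and MT1X (0.88 ± 0.31) were higher in monocytes over the list alone. Free RNA could make up a fraction of 0.702 and 0.521 of the monocyte counts of DDIT4 and MT1X. CYP2E1 in hepatocytes (1.13 ± 0.36) did not pass on either scale. The erythrocyte and plasma cell lists had fewer than 5 measured members in every class and were not tested.

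**Figure D4:**
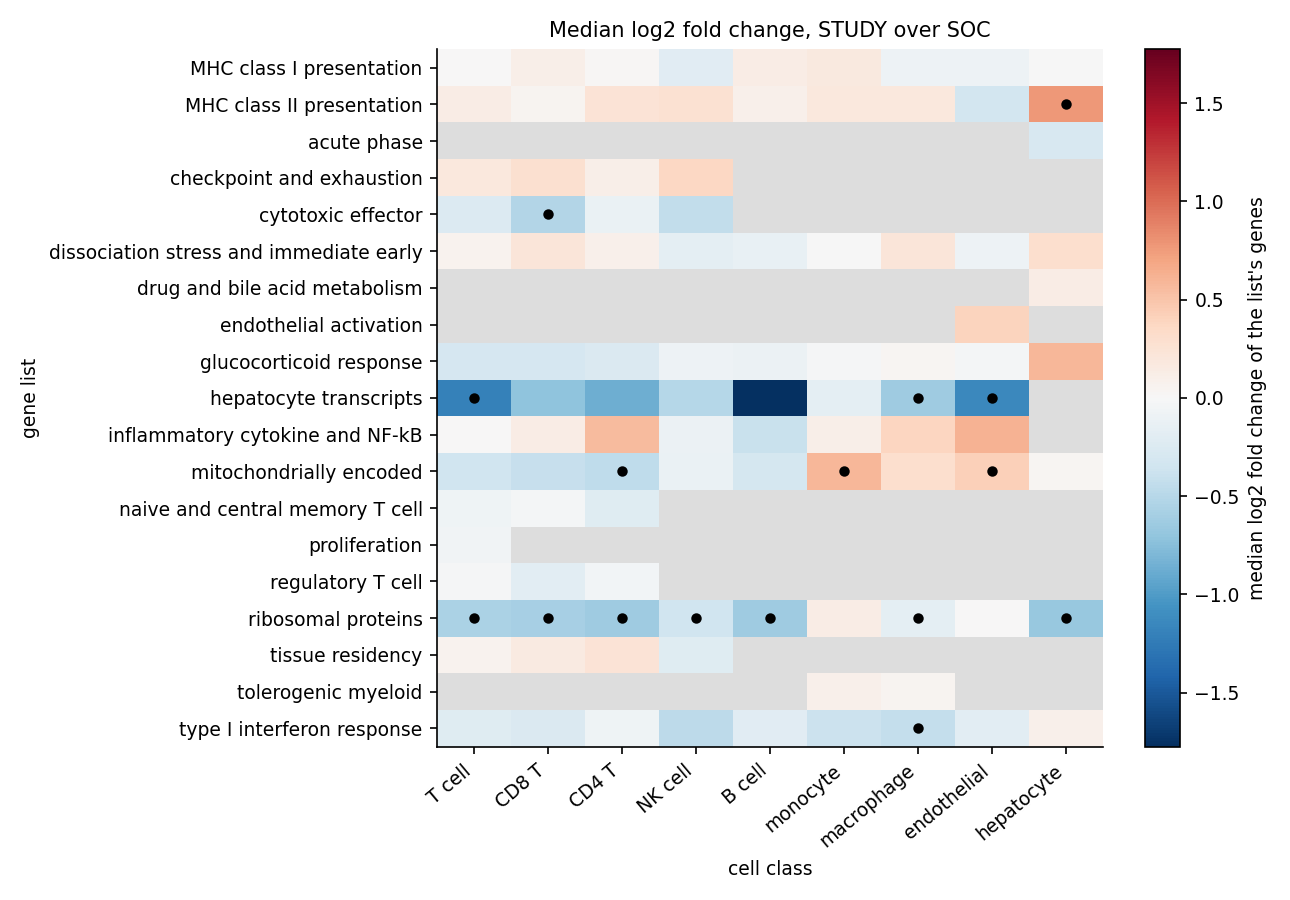
Median log2 fold change (STUDY over SOC, colour scale) of each fixed gene list (vertical axis) in each cell class (horizontal axis), with black dots on the 16 pairs past the threshold in camera and grey where no test was made. Ribosomal proteins carry 7 of the dots, all lower in STUDY.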

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

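The tests of a shared chemistry or gene list behind the called genes, of the hepatocyte part of the ribosomal pattern and of STUDY replicate 4 were chosen after the results had been seen. The count of T cell receptor beta UMIs replaced an earlier form that the differing gene lists had made void.

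Of the 68 genes called in any of the 9 cell classes 51.5% shared exonic sequence with another gene, 5.01 times the share among the other genes tested (Fisher's exact p 3.08e-17), so the way shared sequence was counted may account for many of them. A differing gene list alone cannot account for the 30 T cell calls, since all of them also passed for STUDY replicates 2 and 3, which share the SOC gene list. The 30 were picked partly from those libraries, and that fit called 3550 genes, so passing there decides nothing between chemistry and therapy. In NK cells, hepatocytes and endothelial cells not all calls passed within the SOC gene list. In NK cells 3 of the 4 called genes without a shared exon did. The folds of 17 genes called in T cells correlated between T cells and monocytes (Pearson's r 0.859, across genes, which are not independent replicates), against 0.534 over all 7418 genes tested in both, but the 17 were picked for their T cell folds. Of 8 genes called in T cells without a shared exon, 6 passed both for STUDY replicates 2 and 3 and for STUDY replicate 1 alone, which decides nothing, since the 8 were picked from these libraries and both fits use the same SOC libraries. An effect of the therapy on those genes and technique cannot be told apart, since no STUDY library shared both lists with the SOC libraries.

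Splitting the libraries in other ways gave fewer calls in lymphocytes. Among 35 splits the real one gave 30 genes in T cells and the highest other 1, splits that part the same-numbered libraries included. The counts were 41 and 1 in CD8 T cells, 19 and 1 in CD4 T cells, 19 and 2 in NK cells and 17 and 1 in B cells. They were 5 and 0 in monocytes and 4 and 3 in hepatocytes. Rank 1 of 35 is the best that these splits can give, and the counts were ranked in 9 classes without adjustment. The other splits also mixed STUDY and SOC library techniques within a group, so these ranks exclude neither chance nor technique. In macrophages the real split gave 7 genes and another gave 16 (2 of 35 as large), and in endothelial cells 1 and 4 (4 of 35), so it did not rank first there. For the gene lists the real split gave 16 past the threshold, the highest other gave 54, and 34 of 35 splits gave as many. The split with the most calls in macrophages and lists put STUDY replicates 1 and 4 with SOC replicates 3 and 4. It was picked as the highest of 35, and whether it reflects a structure of the samples other than therapy was not tested.

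Ribosomal protein transcripts were lower in STUDY T cells, B cells and hepatocytes in camera (adjusted p = 0.955 with an estimated correlation), and in B cells no member passed over the list alone. In T cells the median fold was -0.744 for STUDY replicates 2 and 3 and -0.227 for STUDY replicate 1. At least 56.6% of T cell receptor beta UMIs lay on variable genes in STUDY replicates 2 and 3, against at most 6.52% in the SOC libraries, which is consistent with 5' capture in those libraries. That chemistry may lower ribosomal transcripts in T cells, but the same libraries stood at 0.089 and 0.148 in monocytes. Those values argue against an effect alike in all cell types. In T cells STUDY replicate 1 stood at -0.228 from the SOC mean and the SOC libraries at -0.28 to 0.30. Each SOC library was measured from the mean of the other SOC libraries, which widens their range. Whether STUDY replicate 1 lay within the SOC spread is therefore not settled, and both chemistry and therapy stay open. In hepatocytes the median among libraries of 1 barcode list was -0.619. SOC replicate 4 also lay low there, at -0.668 by the measure that widens SOC distances, and the STUDY libraries lay at -0.477 to -0.728. Chemistry and therapy cannot be told apart in hepatocytes.

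STUDY replicate 4 was rich in myeloid cells, with 20.4% macrophages (15.8 to 25.6) and 3.64% T cells. With at most 50% mitochondrial UMIs its macrophage share was 6.61% and its T cell share 27.9%, so the filter on mitochondrial UMIs may account for its makeup. Of these T cells 284 lay in an unnamed sub-cluster led by FCER1G, LGALS3 and TYROBP, at a median relative depth of 0.48. The cells kept in this library at that limit had a median of 39.4% mitochondrial UMIs, so the identity of many of them is uncertain. Cells kept rose 8.585 times there between the 25% and the 50% limit, against 1.09 to 1.315 times in the SOC libraries. Without it the STUDY libraries had 1.44 percentage points more macrophages than SOC, and an effect of the therapy and the spread between patients cannot be told apart.

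Other libraries stood apart from the rest of their group. Among 157 groups of 4 libraries 13 had an outlying library, where chance gives about 1 in 20, or 8. B cells made up 10.43% of SOC replicate 3 (others 3.009% to 3.323%), and MAIT cells, T cell sub-cluster 6, made up 31.1% of its T cells (others 1.7% to 6.678%). In STUDY replicate 4, plasmacytoid dendritic cells made up 2.545% (others 0.2768% to 0.5667%), endothelial cells 14.55% (1.661% to 2.125%), cholangiocytes 7.636% (0.4817% to 0.7179%) and unnamed cells 8.00% (2.04% to 3.026%). Their exact 95% Clopper-Pearson intervals were 9.44 to 11.5 for the B cells, 28.9 to 33.4 for the MAIT cells, and 1.03 to 5.17, 10.6 to 19.3, 4.79 to 11.4 and 5.08 to 11.9 for the last 4. PTPRCAP in B cells stood at 1.727 CPM in SOC replicate 2 and at 0 in the other SOC libraries. POLD4 in macrophages stood at 177.2 CPM in STUDY replicate 2 (others 116.9 to 123.6), AGGF1 in hepatocytes at 106.2 CPM in STUDY replicate 2 (26.51 to 35.01) and AK1 in hepatocytes at 12.28 CPM in SOC replicate 1 (2.048 to 3.208). SOC replicate 2 had 33892071 UMIs (other SOC libraries 53496033 to 57100301) and a median of 10.5% mitochondrial UMIs (14.5% to 14.8%). Outside the gene comparisons, T cell receptor beta UMIs lay on variable genes in 67.61% of STUDY replicate 2 and 56.56% of STUDY replicate 3, against 2.962% to 6.517% in SOC libraries.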

How the results depend on the processing

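The fits within 1 gene list, of STUDY replicate 1 alone, without genes that share exons, with doublets removed at the expected rate and with both an estimated correlation and the replicate block were chosen after seeing the data. No named gene changed direction in any alternative that measured it: of their log2 folds 1494 kept their side of the threshold, 336 lost it and 51 gained it. The naming rule asked for the same direction in every fit that leaves out 1 library. Those fits could therefore show no reversal for a gene that passed the rule. Of the gene list tests 244 kept theirs, 83 lost it and 3 turned direction. Of the differences in shares 259 kept their direction and 28 did not. Some alternatives repeat a fit, so these tallies count some results more than once. In T, CD8 T, CD4 T, NK and B cells the fit within 1 gene list is that without STUDY replicate 1. A minimum of 10 cells per library repeats the main fit in every class but T cells. Unless said below, the cause was not tested.

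With DESeq2 the counts of called genes were 475 in T cells, 166 in CD8 T cells, 69 in CD4 T cells, 60 in NK cells, 42 in B cells, 206 in monocytes, 24 in macrophages, 6 in endothelial cells and 25 in hepatocytes (edgeR 30, 41, 19, 19, 17, 5, 7, 1 and 4). DESeq2 called 25 of the 30 edgeR calls, 38 of 41, 13 of 19, 19 of 19, 17 of 17, 2 of 5, 7 of 7, 1 of 1 and 0 of 4. The missing 5, 3, 6, 3 and 4 in T, CD8 T and CD4 T cells, monocytes and hepatocytes had no adjusted p in DESeq2, and none of the calls failed with one. DESeq2 split the counts into 40 higher and 20 lower in NK cells, 122 and 84 in monocytes, 2 and 4 in endothelial cells and 6 and 19 in hepatocytes. With limma-voom and sample weights they were 2102, 1309, 436, 957, 371 and 295 in T, CD8 T, CD4 T, NK, B cells and monocytes and 4 in macrophages. The first 6 split into 1101 higher and 1001 lower, 687 and 622, 251 and 185, 512 and 445, 207 and 164, and 167 and 128. Without a filter on low counts they were 210, 649, 321, 375, 177, 528, 141, 87 and 117 in the order given for DESeq2, which split into 150 higher and 60 lower, 347 and 302, 180 and 141, 223 and 152, 88 and 89, 274 and 254, 91 and 50, 56 and 31, and 59 and 58. RLE size factors gave 8 in monocytes.

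Without genes that share exons the counts in edgeR were 2, 0, 1, 0, 1, 0, 0, 0 and 0 in that order, because most called genes were left out and the remaining p-values were adjusted without them. Within 1 gene list they were 3550, 2280, 1319, 2204, 709, 1437, 686, 25 and 247, within 1 barcode list 47 in monocytes, 19 in macrophages, 13 in endothelial cells and 8 in hepatocytes, and for STUDY replicate 1 alone 135, 107, 104, 169 and 29 in T, CD8 T, CD4 T, NK and B cells. Leaving out 1 library gave 14 to 3550 in T cells, 12 to 2280 in CD8 T cells, 10 to 1319 in CD4 T cells, 1 to 2204 in NK cells, 5 to 709 in B cells, 3 to 878 in monocytes, 2 to 57 in macrophages, up to 8 in endothelial cells and 2 to 40 in hepatocytes. The highest count was that without STUDY replicate 1 in every class.

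With at most 10% mitochondrial UMIs the counts were 16 in CD8 T cells, 36 in monocytes and 8 in hepatocytes. With at most 50% they were 13 in T cells, 9 in B cells, 17 in monocytes, 0 in endothelial cells (edgeR) and 10 in hepatocytes. The graph not balanced over libraries gave 27 in CD8 T cells, 36 in CD4 T cells, 8 in B cells, 13 in monocytes, 1 in macrophages and 2 in endothelial cells. Classes assigned per cell gave 27 in CD8 T cells, 11 in NK cells and 9 in monocytes. No doublet removal gave 6 in B cells and 8 in monocytes, and removal at the expected rate 5 in B cells. A minimum of 10 cells per library gave 66 in T cells, and leaving out genes with a free-RNA share of 50% or more gave 17 in monocytes.

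Of the gene lists 16 passed, 0 with an estimated correlation in camera, 0 with that correlation and the replicate block, 0 in fry, 10 of the 88 pairs testable without genes of a high free-RNA share (11 of these pairs passed otherwise, 10 of them in both) and 7 of the 66 testable for STUDY replicate 1 alone (8 otherwise, 4 in both). Leaving out 1 library gave 14 to 25, the highest without SOC replicate 2. The MHC class II presentation list turned direction in hepatocytes with classes assigned per cell (adjusted p 0.992), the mitochondrial list in CD4 T cells with at most 50% mitochondrial UMIs (0.246) and the ribosomal list in NK cells for STUDY replicate 1 alone (0.629).

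No cluster was named cholangiocyte or left unnamed with at most 10% mitochondrial UMIs, and no cell was unnamed with classes assigned per cell, so no difference could be given there. No share passed, and several differences (STUDY minus SOC, percentage points) changed sign. With at most 10% mitochondrial UMIs the T cell difference was 7.41 instead of -17.0, monocytes -1.89 instead of 3.58, endothelial cells -2.17 instead of 1.54 and cycling cells -0.261 instead of 1.75. With at most 50% it was 0.103 for B cells (instead of -1.76), 3.28 for CD4 T cells (-1.32), -7.79 for CD8 T cells (4.38), -2.665 for endothelial cells and -1.12 for unnamed cells (1.40). On a centred log-ratio scale it was 0.461 for CD4 T cells, -0.287 for endothelial cells and -0.520 for NK cells (4.402), and with classes assigned per cell 4.84 for CD4 T cells. Within 1 gene list it was -0.154 for cholangiocytes (1.53), -1.70 for endothelial cells and -0.023 for plasmacytoid dendritic cells (0.545), and within 1 barcode list 0.298 for hepatocytes (-0.928).

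Leaving out 1 library also turned signs. The differences then ran from -2.44 to 0.063 for B cells, -4.66 to 5.19 for CD4 T cells, -0.262 to 10.5 for CD8 T cells, -0.224 to 2.16 for cholangiocytes, -1.61 to 2.69 for endothelial cells, -0.531 to 0.174 for erythroid cells, -2.54 to 1.83 for hepatocytes and -0.534 to 9.66 for NK cells. Without SOC replicate 3 the B cell difference was 0.063, without SOC replicate 4 the CD8 T cell difference -0.262, the erythroid one 0.174 (instead of -0.247) and the hepatocyte one 1.83. Without STUDY replicate 2 the hepatocyte difference was 1.497 and the CD4 T cell one 5.19, and without SOC replicate 1 the CD4 T cell one 0.389. Without STUDY replicate 4 it was -0.224 for cholangiocytes and -1.61 for endothelial cells, and for NK cells it was -0.284 without STUDY replicate 1 and -0.534 without STUDY replicate 3.

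With the replicate block the counts of called genes were 25, 18, 3, 16, 13, 11, 7, 0 (edgeR) and 1 in T, CD8 T, CD4 T, NK, B cells, monocytes, macrophages, endothelial cells and hepatocytes, and 26 gene lists passed, 15 of them among the 16. Of the calls made without the block these held 17 of 30, 14 of 41, 3 of 19, 7 of 19, 8 of 17, 5 of 5, 6 of 7, 0 of 1 and 1 of 4. In T cells every pair of libraries with the same number correlated (0.128 to 0.159) and 6 of 6 libraries correlated best with their own number, so the blocked values stand beside that result, where the block split the calls into 15 higher and 10 lower instead of 24 and 6. It split them into 13 and 5 in CD8 T cells, 3 and 0 in CD4 T cells, 8 and 8 in NK cells (16 and 3 without it), 8 and 5 in B cells and 9 and 2 in monocytes. This is a hint from the data and not the design, since the patients differ. In T cells the type I interferon response list also passed with the block (adjusted p 0.00835, and adjusted p = 0.983 with an estimated correlation), and no other list there changed its call. In the other classes not every pair reached 0.1, and the libraries that correlated best with their own number were 5 of 6 in CD8 T, 1 of 6 in CD4 T, 4 of 6 in NK and 5 of 6 in B cells, 2 of 8 in monocytes, 3 of 8 in macrophages, 0 of 8 in endothelial cells and 2 of 8 in hepatocytes.

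Depth was lowest in STUDY replicates 2 and 3, with 11044528 and 16374422 UMIs. STUDY replicate 4 had the most, 87441965, but at the 25% limit on mitochondrial UMIs its 275 cells were too few for the T, CD8, CD4, NK and B cell fits.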

Other observations

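The test of T cell sub-cluster 1 was chosen after the results had been seen. T cell sub-cluster 1, led by GZMK, CD8B and CD8A, made up 25.3% ± 2.94 (SD, n = 3) of STUDY and 14.1% ± 3.00 (SD, n = 4) of SOC T cells. It was the sub-cluster with the smallest p of 10, higher in all 3 STUDY libraries than in any SOC library, with an exact permutation p of 0.0571, the smallest possible, and an adjusted p of 0.571. Single libraries had 25.8% (23.5 to 28.2), 22.1% (19.8 to 24.5) and 27.9% (23.6 to 32.5) in STUDY and 14.9% (13.3 to 16.7), 15.9% (14.5 to 17.4), 16.05% (14.3 to 17.9) and 9.71% (8.44 to 11.1) in SOC (95% Clopper-Pearson, counting error only). Leaving out 1 library gave differences of 9.64 to 12.7 percentage points. The share depends on balancing the graph over libraries. With the graph not balanced, the sub-cluster led by GZMK and CD160 held 18, 6 and 4 cells of STUDY replicates 1 to 3 and 401, 211, 435 and 157 of SOC replicates 1 to 4, and 3 other CD8 sub-clusters, of 929, 437 and 187 cells, came almost wholly from STUDY libraries. STUDY replicate 4 had 0 such cells among 10 T cells.

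Of the mitochondrially encoded genes, MT-ATP8 (3.30 ± 0.90) and MT-ND4L (2.14 ± 0.59) were higher in T cells over the list alone while MT-ATP6 stood at -0.96 ± 0.32 and did not pass. In B cells MT-ATP8 (3.29 ± 0.97), MT-ND4L (2.18 ± 0.59) and MT-ND6 (1.42 ± 0.42) were higher and MT-ATP6 (-0.87 ± 0.31) lower over the list alone. MT-ATP8 overlaps MT-ATP6 and MT-ND4L overlaps MT-ND4 on the mitochondrial genome, so their counts are uncertain in the same way as those of other genes that share sequence.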
